A study of Mus musculus with 6 samples.

How the data were processed

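RNA sequencing libraries came from cells sorted out of the femurs of mice at postnatal day 21, per the labels. The growth plates were removed, the remaining bone and marrow were digested with collagenase, and about 20000 cells per library were collected by flow cytometry. Control libraries (n = 3) held GFP+ cells of mice with a GFP knock-in on one Cxcl12 allele and a floxed other allele. CXCL12-deficient libraries (n = 3) held GFP+ tdTomato+ cells of mice that also carried a Col2a1-cre transgene, which recombines the floxed allele and switches on the tdTomato reporter in cells descended from Col2a1-expressing precursors. The gate, the cre transgene and the state of the floxed allele therefore changed together in every library. The labels give no sex, litter, batch or replicate number, so no pairing or block was fitted and the replicate numbers only name the libraries. They do not say that each library came from a separate animal, so the p-values measure the spread between these libraries.

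The authors deposited a table of whole-number read counts per gene, not normalized. The submitters' processing notes name FastQC, TopHat2 2.0.13, Bowtie2 2.2.1, Cufflinks, Cuffdiff, HTSeq and DESeq2 and the mouse genome build mm10, without the role of each tool. The annotation, the strand setting and the treatment of reads shared between similar genes are not given in the sources used here, so counts of overlapping or near-identical genes are uncertain. The library kit named in the labels is Nextera XT. A deposited table of depth-normalized signal equalled the counts divided by 1 size factor per library, and that factor differed from the DESeq2 median-of-ratios factor by at most 1.1e-09. The authors also deposited regularized log2 values. In that log2 table some gene names had been turned into dates, and those entries were left out of the alternative that used it.

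The count table held 17131 entries. Among the entries used here none carried the name of a ribosomal protein gene of the Rpl or Rps series or of a mitochondrially encoded gene, so CPM and shares of counts are relative to totals without them, and RNA quality was not analysed here. Cxcl12 appeared as 4 exon entries and not as a gene, so the 4 were summed to 1 gene, which left 17128 genes. The exons were also fitted separately as deposited. The edgeR filter (filterByExpr, minimum count 10, minimum total count 15) kept 13926 genes. Total counts ran from 20133299 to 28009257 per library, so 1 read was worth between 0.0357 and 0.0472 CPM (counts scaled to a common library total). CPM were scaled by TMM factors, which lay between 0.955 and 1.05.

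CXCL12-deficient libraries were compared with controls by the robust quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors (SE) of log2 fold changes came from the F statistic. Single values were also compared by exact two-sided permutation of the 6 libraries, for which 3 against 3 gives p = 0.1 at the smallest. The tests covered 32 lists of genes, of stromal programmes and of other cell types that a sort of marrow could hold, all written before the data were examined. They used camera in limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry. List members were also adjusted over the list alone. Of 607 listed genes, 23 were matched to no entry and 14 were found under an older symbol.

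The named genes follow a rule fixed before the data were examined. It took Cxcl12 and the 12 genes with the largest log2 fold change in each direction among called genes with a mean of at least 5 CPM, no overlap between the groups and a proper gene name. From each list it took up to 4 called members with the largest change or, where none was called, the 2 most abundant. Xist and Y-linked genes served as a check of sex. An item that the rule took is not reported here.

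The steps were tested on simulated counts with the means and library sizes of these libraries, with 200 genes changed. In the simulated comparison of 13684 genes, 7.5% of the genes changed 1.5-fold, 28.4% of those changed 2-fold and 81.8% of those changed 4-fold were recovered. Of 82 genes called, 4 were false. Simulated genes were drawn independently of each other, so these shares need not hold for real genes that vary together. Alternatives were DESeq2 size factors, upper quartile factors, no filter beyond 1 read, a filter of 5 CPM in 3 libraries, no robust shrinkage, DESeq2 1.42.0, limma-voom, limma on the deposited log2 values, an adjusted p below 0.01, and leaving out each library. Coordinates are those of GENCODE M21 on GRCm38, which may differ from the annotation the authors used.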

Results

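The series asked what changes in the transcriptome of marrow stromal cells of the femur when CXCL12 is lost. CXCL12 is the chemokine that retains blood-forming cells in the marrow, and the stromal cells that make most of it are known as CXCL12-abundant reticular (CAR) cells. Gene expression was measured by RNA sequencing in 3 control libraries of GFP+ cells and 3 CXCL12-deficient libraries of GFP+ tdTomato+ cells, all from mice at postnatal day 21. Total counts of the control libraries were 28009257, 24214000 and 20133299, and those of the CXCL12-deficient libraries 25155012, 23093189 and 22865174. Between 15074 and 15908 entries of the table had at least 1 read in a library.

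Cxcl12 itself was 2.91-fold lower in the CXCL12-deficient libraries, and its exons fell unevenly. The summed exons gave 3747 ± 112 CPM in controls and 1289 ± 130 CPM in CXCL12-deficient libraries (SD, n = 3 each), a log2 fold change of -1.54 ± 0.17 (SE; adjusted p = 0.0053, edgeR). Exon 2 lost the most, from 385 ± 24.7 to 26.3 ± 7.15 CPM, which left 6.8% of the control level (log2 fold change -3.87 ± 0.22, adjusted p = 0.00027). Exon 3 kept 17% (-2.56 ± 0.15, adjusted p = 0.00027) and exon 4 kept 37.8% (-1.40 ± 0.17, adjusted p = 0.0053). Exon 1 kept 59.4% (-0.75 ± 0.15, adjusted p = 0.024), and this call was made in only 1 of the 6 refits that left out a library, the one without control replicate 1. The log2 ratio of exon 2 to exon 1 was 1.20 ± 0.07 in controls and -1.95 ± 0.47 in CXCL12-deficient libraries (SD; exact permutation p = 0.1, two-sided, the smallest this design allows). Every control library exceeded every CXCL12-deficient library at each of the 4 exons.

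In GENCODE M21 the gene lies on the plus strand of chromosome 6, from 117168535 to 117181367 of GRCm38, and encodes a small secreted protein. In the transcript Cxcl12-203, exon 2 spans 117171482 to 117171599 and exon 3 spans 117173492 to 117173578, both fully coding. Exon 1 of that transcript, 117168574 to 117168716, holds the start of the coding sequence. Exon 4 spans 117178583 to 117181366 and is mostly 3' UTR. In Cxcl12-201 exon 4 begins earlier, at 117176086. The borders the authors used for their exon entries, and the floxed exon, are not given in the sources used here. Each control cell already carried GFP on one Cxcl12 allele, and GFP driven from Cxcl12 defined both gates.

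**Figure D1:**
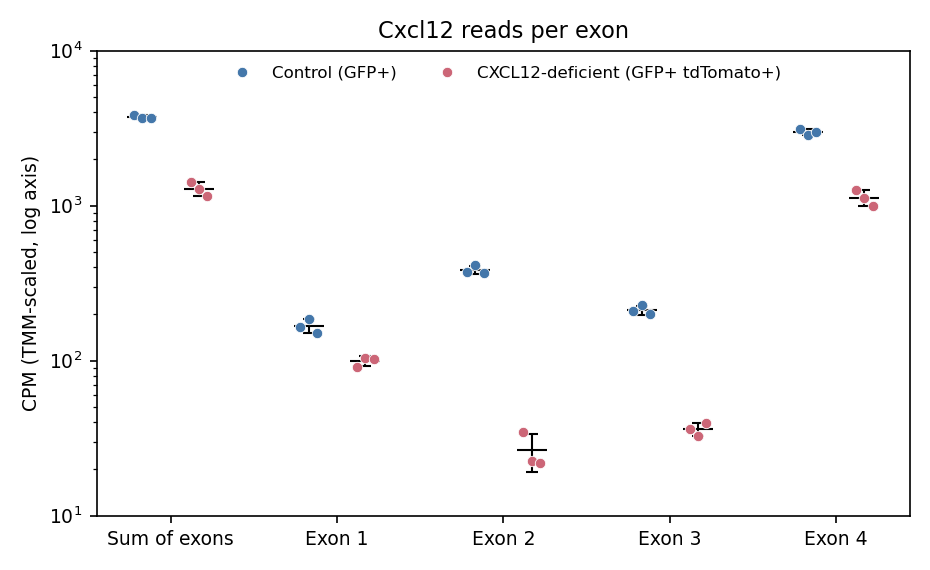
Cxcl12 reads per library, in TMM-scaled CPM on a log axis, for the sum of the 4 exon entries and for each exon. Points are libraries (3 control, 3 CXCL12-deficient), horizontal bars are means and whiskers are SD. Exon 2 fell from a mean of 385 to 26.3 CPM, and exon 1 from 168 to 99.7 CPM.

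Across the transcriptome, more genes were lower than higher in the CXCL12-deficient libraries. All 15 neutrophil genes and 10 of 22 endothelial genes fell, 0 of 13 erythroid genes was called by edgeR, and 4 of 27 niche genes rose. Of 13926 genes, 637 differed (adjusted p below 0.05, edgeR), 548 of them lower and 89 higher. The lower genes had a median log2 fold change of -2.02 and the higher genes one of 0.88. At least 2-fold differences were found for 506 lower and 32 higher genes. The groups did not overlap at any of the 637 genes. Of all tested genes 25.6% did not overlap, where chance gives 10% for 3 against 3. The count depended on which library was left out: 74 genes were called without control replicate 3, 160 without control replicate 2, 577 without control replicate 1, and 493, 488 and 479 without CXCL12-deficient replicates 1, 2 and 3. The number of higher genes was 47 without control replicate 1, 6 without control replicate 2 and 37 without CXCL12-deficient replicate 1. Without control replicate 3 edgeR called 0 genes higher, with 515 higher at an unadjusted p below 0.05, 118 by DESeq2 and 7 by limma-voom. All 637 genes had the sign of the full comparison in each of the 6 refits, which the lack of overlap between the groups all but fixed in advance.

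Some genes of stromal identity and of the blood-forming niche were higher in the CXCL12-deficient libraries. In the list of CAR cell and niche genes, 4 of 27 members rose, and 8 rose when adjusted over the list alone. In all 26 of 27 had a positive log2 fold change, with a median of 0.45. Of the 27, 11 were also in another list, so the lists are not independent. Among them were Adipoq, also in the lipid list, and Cxcl14, also in the chemokine list. Apoe, which encodes a lipid carrier protein, went from 2082 ± 277 to 5138 ± 752 CPM, a log2 fold change of 1.30 ± 0.20 (adjusted p = 0.011). Cxcl14, a chemokine gene, rose 1.99-fold from 1106 to 2206 CPM (adjusted p = 0.028). Adipoq, which encodes adiponectin, was 1.97-fold higher (adjusted p = 0.038), and Ebf3, a transcription factor of CAR cells, was 1.64-fold higher (adjusted p = 0.023). Chosen after their values were seen, Lepr (leptin receptor) and Il7 (a lymphoid growth factor) had log2 fold changes of 0.72 ± 0.19 and 0.91 ± 0.26. Their adjusted p was 0.075 and 0.093 over all genes, and 0.021 and 0.025 over the list alone. The camera test placed the list above other genes (adjusted p = 7.2e-09), but not with an estimated correlation (adjusted p = 0.23), and directional fry gave adjusted p = 0.069. In the same libraries the 15 neutrophil genes took 2.0% ± 0.359 of the counts in controls and 0.446% ± 0.23 in CXCL12-deficient libraries (SD, n = 3). The called niche members numbered 2 without control replicate 1, 1 without control replicate 2, 0 without control replicate 3, 1 without CXCL12-deficient replicate 1 and 6 without CXCL12-deficient replicate 2.

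Most lipid metabolism genes had a positive log2 fold change, few were called, and 1 of the called genes fell. Of 27 genes of fat cell differentiation and lipid storage, 3 rose and 1 fell, with the same 4 called when adjusted over the list alone. In all 20 of the 27 had a positive log2 fold change, with a median of 0.38. Among the 3 that rose was Adipoq, already counted in the niche list. Gpd1, the glycerol-3-phosphate dehydrogenase of triglyceride synthesis, showed the largest rise among the named genes, from 5.96 ± 3.29 to 50.6 ± 32.7 CPM, or 8.52-fold (log2 fold change 3.09 ± 0.60, adjusted p = 0.023). Cfd, encoding adipsin, was 6.06-fold higher at a low level (1.08 against 6.63 CPM, adjusted p = 0.047). Dgat2, which catalyses the last step of triglyceride synthesis, fell from 96.8 to 40.7 CPM (log2 fold change -1.25 ± 0.29, adjusted p = 0.044). The insulin-responsive glucose transporter gene Slc2a4, outside the list, was 3.47-fold higher (adjusted p = 0.017). Gpd1, Cfd, Dgat2 and Slc2a4 were called in 1, 2, 1 and 4 of the 6 refits. The adipocyte regulator Pparg, named after its value was seen, had 155 CPM in controls and 195 CPM in CXCL12-deficient libraries (adjusted p = 0.35). The list passed camera at adjusted p = 0.0044, and had adjusted p = 0.46 with an estimated correlation and adjusted p = 0.26 by directional fry. Its called members numbered 1 without control replicate 1 or CXCL12-deficient replicate 1, 0 without control replicate 2 or 3, and 2 without CXCL12-deficient replicate 2 or 3.

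Other named genes were also higher. Il34, a ligand of the macrophage growth factor receptor, rose 2.68-fold from 81.0 ± 13.5 to 217 ± 35.0 CPM (adjusted p = 0.0069) and lost its call only without control replicate 3. The Wnt antagonist genes Sfrp4 and Sfrp1 were 3.0-fold and 1.57-fold higher (adjusted p = 0.020 and 0.045), the only 2 of 21 Wnt genes called. No Wnt gene was called without control replicate 1, 2 or 3 or CXCL12-deficient replicate 1, and 1 was without CXCL12-deficient replicate 3. Sfrp4 was called in 2 of the 6 refits. Bmper, encoding a BMP-binding protein, was 2.13-fold higher (adjusted p = 0.014), 1 of 23 BMP and TGF-beta genes. Serping1, the C1 inhibitor gene, was 1.84-fold higher (adjusted p = 0.036), while C3 and Cfp of the same complement list fell by 2.16 and 1.17 on the log2 scale. The natriuretic peptide receptor gene Npr1 was 3.43-fold higher (adjusted p = 0.023) and the adenylate cyclase gene Adcy2 2.32-fold higher (adjusted p = 0.038). Fam69c, Pcdhb7 (a protocadherin) and H2-Q10 (an MHC class I gene whose family shares similar sequence) were 2.43-fold, 2.37-fold and 2.32-fold higher. Sfrp1, Serping1 and Pcdhb7 were called in none of the 6 refits without a library, and without control replicate 3 the only call among these genes was C3.

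**Figure D2:**
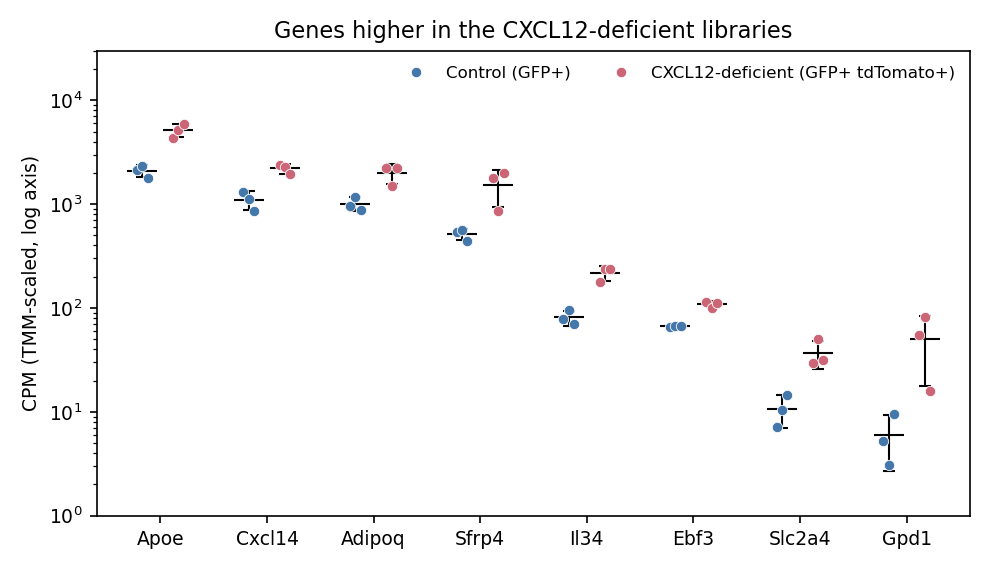
Levels of 8 genes that were higher in the CXCL12-deficient libraries, in TMM-scaled CPM on a log axis. Points are libraries (3 per group), horizontal bars are means and whiskers are SD. Gpd1 spread from 16.0 to 81.1 CPM among CXCL12-deficient libraries, and Ebf3 from 100.4 to 113.8 CPM.

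Genes of the granulocyte lineage were lower throughout. All 15 measured neutrophil genes fell, with a median log2 fold change of -2.10, and all 15 also passed when adjusted over the list alone. Mpo, the myeloperoxidase gene of granulocyte precursors, went from 3040 ± 911 to 539 ± 296 CPM (log2 fold change -2.50 ± 0.39, adjusted p = 0.012). Mmp8, Csf3r (the receptor of granulocyte colony-stimulating factor) and Retnlg fell by 2.53, 2.43 and 2.38 on the log2 scale. The list passed camera (adjusted p = 7.7e-18) and directional fry (adjusted p = 0.040), but had adjusted p = 0.23 with an estimated correlation. Its called members numbered 4 without control replicate 2, 2 without control replicate 3 and 7 without CXCL12-deficient replicate 2.

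Other blood lineage lists differed in how many of their genes were called. Of 18 monocyte and macrophage genes 8 fell, among them Lyz2 (lysozyme, 2327 against 432 CPM), Ptprc (the pan-leukocyte antigen CD45, -2.61 ± 0.28), Itgam and Cd14. When adjusted over that list alone, 10 fell and 1 rose. The one that rose was the complement gene C1qc, named after its value was seen (log2 fold change 0.78, adjusted p = 0.028 over the list alone and 0.15 over all genes). In all 7 of the 18 had a positive log2 fold change. Of 8 megakaryocyte genes 6 fell, and 8 when adjusted over the list alone. Ppbp dropped by 5.91 and Pf4 by 4.58 on the log2 scale, and Gp1ba was 11.6-fold lower. With 1 library left out, their log2 fold changes ran from -6.32 to -4.79, from -4.94 to -3.89 and from -4.40 to -2.94, and Gp1ba was called in 1 of the 6 refits. Of 12 B lineage genes 3 fell (Rag1, Cd79a and Blnk), with 12 lower when adjusted over the list alone. Nkg7 was the only 1 of 8 T and NK cell genes called, with 6 lower when adjusted over the list alone. The macrophage, megakaryocyte, B lineage and T and NK cell lists had camera adjusted p of 6.5e-05, 7.9e-07, 6.3e-08 and 0.00055, and adjusted p = 0.51, 0.35, 0.40 and 0.23 with an estimated correlation. Directional fry gave adjusted p = 0.081, 0.076, 0.11 and 0.048. Without control replicate 3, 3 macrophage, 3 megakaryocyte and 0 B lineage genes were called. Without control replicate 1, 8 B lineage genes were. The B lineage count was 0 without control replicate 2 or CXCL12-deficient replicate 1 or 2, and 1 without CXCL12-deficient replicate 3. The megakaryocyte count was 3 without control replicate 2. The T and NK cell count was 2 without CXCL12-deficient replicate 2 and 0 without any other library.

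Erythroid genes did not share this fall. None of 13 was called by edgeR, DESeq2 or limma-voom, 0 passed at an unadjusted p below 0.05, and the median log2 fold change was -0.06. The haemoglobin gene Beta-s had 846 ± 251 CPM in controls and 1425 ± 1145 CPM in CXCL12-deficient libraries. Alas2, of haem synthesis, had 1102 and 1965 CPM. It passed the threshold only without CXCL12-deficient replicate 3 (log2 fold change 1.27, adjusted p = 0.022). The adjusted p of Alas2 was 0.40 in the full comparison.

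Part of the endothelial list was lower. Of 22 members 10 fell, and 14 when adjusted over the list alone, with a median of -1.78. Esam, a junction adhesion gene, went from 21.6 to 2.64 CPM (-3.03 ± 0.29, adjusted p = 0.0039) and stayed called in all 6 refits. Cdh5 (VE-cadherin) and Emcn were 11.8-fold and 6.06-fold lower from control levels under 10 CPM, and were called in 3 and 1 of the 6 refits. Sox17 was called in 1, and the size of its fall was unsettled: it had reads in only 1 CXCL12-deficient library, and its log2 fold change of -5.54 ran from -10.60 to -4.56 when 1 library was left out. The list had camera adjusted p = 2.9e-11, adjusted p = 0.23 with an estimated correlation and adjusted p = 0.039 by directional fry. Its called members numbered 6 without control replicate 1, 4 without control replicate 2 and 3 without control replicate 3. Of 10 fibroblast and tendon genes 4 fell, and the same number when adjusted over the list alone: Ly6c1 (26.3-fold), Cd34 (11.7-fold), Ly6a and Pi16. Endothelial and blood progenitor cells also carry the first 3 of these. That list had camera adjusted p = 0.0011, adjusted p = 0.23 with an estimated correlation and adjusted p = 0.039 by directional fry. Its count was 2 without control replicate 2, control replicate 3, CXCL12-deficient replicate 2 or CXCL12-deficient replicate 3. The receptor gene Cxcr4 and the CXCL12-cleaving protease gene Dpp4 fell by 1.72 and 2.52 on the log2 scale, 2 of 4 in the list of CXCL12 receptors. That list had camera adjusted p = 0.0033, adjusted p = 0.23 with an estimated correlation, adjusted p = 0.039 by directional fry, and no called member without control replicate 2 or 3 and 1 without CXCL12-deficient replicate 1 or 2. Cxcr4 and Dpp4 rose from control replicate 1 to 2 to 3, as the leukocyte gene Ptprc did (59.8, 75.4 and 107 CPM). The uncalled erythroid gene Slc4a1, chosen after its values were seen, did so too (380, 542 and 773 CPM), while Beta-s did not. That order therefore does not single out leukocytes. In CXCL12-deficient replicates 1, 2 and 3, Ptprc had 12.7, 16.9 and 10.2 CPM, Dpp4 5.4, 5.8 and 2.0, and Cxcr4 7.08, 5.89 and 4.93. In which cells Cxcr4 and Dpp4 fell was not tested. Among the 12 largest decreases were also Amica1, Sh3tc1, Lilra6, F10, Dennd1c and Clec4d, between 9.25-fold and 15.1-fold lower and called in 5, 2, 4, 2, 5 and 2 of the 6 refits. With 1 library left out, the log2 fold change of Sh3tc1 ran from -4.92 to -3.12 and that of F10 from -4.71 to -2.92. F2rl2, at -5.14, ran from -8.74 to -3.93 and was called in 1 refit.

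Few cell cycle and interferon response genes were called by edgeR. DESeq2 called 11 of 30 cell cycle and 10 of 30 interferon genes, and limma-voom 3 and 1. All 30 cell cycle genes had a negative log2 fold change (median -0.74). Of these, 3 fell (Top2a, Kif23 and Tpx2, by 1.24, 1.22 and 1.06 on the log2 scale), and 21 when adjusted over the list alone. The list had camera adjusted p = 2.5e-11, adjusted p = 0.51 with an estimated correlation and adjusted p = 0.19 by directional fry. Blood lineage genes were lower in the same libraries, as given above. In control replicates 1, 2 and 3, Top2a had 60.7, 82.2 and 119 CPM, and Cd79a of the B lineage 98.8, 194 and 255 CPM. In CXCL12-deficient replicates 1, 2 and 3, Top2a had 38.7, 39.3 and 32.7 CPM, and Cd79a 71.5, 55.9 and 24.9 CPM. The uncalled erythroid gene Slc4a1 also rose across the controls, as given above, so this order does not single out the B lineage. In which cells the cell cycle genes fell was not tested. Without control replicate 1, 10 cell cycle genes were called. The count was 1 without CXCL12-deficient replicate 2 and 0 without any of the other 4 libraries. Of 30 interferon genes 2 rose, Ifi44 (2.86-fold) and Ifit1 (2.32-fold), with 8 higher and 1 lower when adjusted over the list alone and a median of 0.59. Ifit1 had 130, 101 and 52.5 CPM in CXCL12-deficient replicates 1, 2 and 3, against 39.8 to 41.6 CPM in controls. Without CXCL12-deficient replicate 3, 13 interferon genes were called. No interferon gene was called without CXCL12-deficient replicate 2 or any 1 control. The list had camera adjusted p = 1e-04, adjusted p = 0.73 with an estimated correlation and adjusted p = 0.48 by directional fry.

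**Figure D3:**
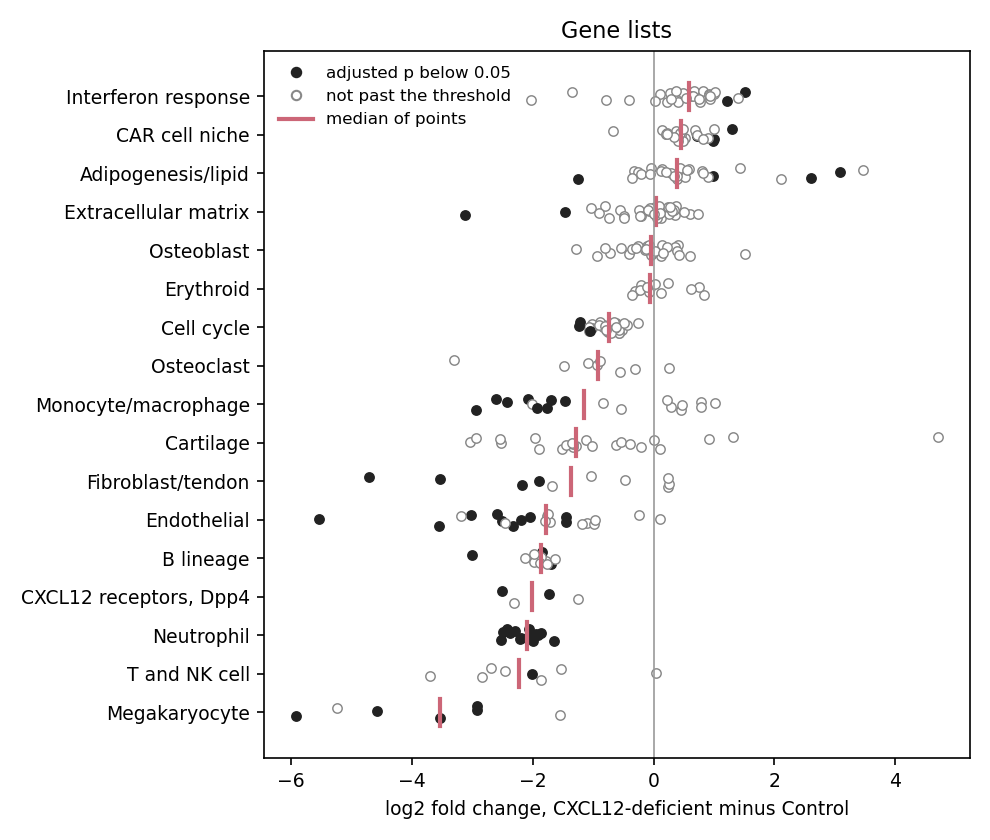
Log2 fold changes (CXCL12-deficient minus control) of the members of 17 gene lists that had reads in both groups, each point a gene. Filled points passed an adjusted p of 0.05 in edgeR, open points did not, and bars are medians of the points drawn, from -3.54 for megakaryocyte genes to 0.59 for interferon response genes.

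Genes of bone formation showed no detectable difference with all libraries, a result that depended on control replicate 1. None of 27 osteoblast genes was called by edgeR, DESeq2 or limma-voom (1 at an unadjusted p below 0.05, median log2 fold change -0.04). Without control replicate 1, however, 2 were called, and without CXCL12-deficient replicate 2, 1. The median log2 fold change of osteoblast and matrix genes outside the niche list was 0.02 with all libraries and 0.37 without control replicate 1. It lay between -0.10 and 0.12 without any other single library. The niche median without control replicate 1 was 0.50. Spp1 (osteopontin) had 7933 ± 4168 and 7502 ± 813 CPM, and Sparc 4471 and 4990 CPM. Col1a1, named after its values were seen, had 9819 CPM in control replicate 1 and 7055 CPM in CXCL12-deficient replicate 2, and between 1249 and 2123 CPM in the other libraries. In the extracellular matrix list 2 of 36 members fell, Fbln2 and Thbs1 (by 3.12 and 1.47 on the log2 scale), both calls being lost without control replicate 3. Cartilage genes varied widely within groups: Col2a1 ranged from 86.9 to 1149 CPM in controls and from 12.3 to 377 CPM in CXCL12-deficient libraries. None of 23 cartilage genes was called by edgeR, DESeq2 or limma-voom, and 0 passed at an unadjusted p below 0.05. Without CXCL12-deficient replicate 1, however, 1 cartilage and 1 osteoclast gene were called. The osteoclast list passed camera (adjusted p = 0.011, adjusted p = 0.29 with an estimated correlation and adjusted p = 0.076 by directional fry) with 0 of 8 genes called by edgeR, 3 at an unadjusted p below 0.05 and 1 by DESeq2. Mmp9 and Ctsk had 737 and 241 CPM in controls and 594 and 287 CPM in CXCL12-deficient libraries.

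Among the remaining lists the called genes were few. Nrarp fell by 1.62 on the log2 scale (1 of 15 Notch genes) and Cd44, an adhesion receptor also carried by leukocytes, by 1.30 (1 of 9 osteocyte genes), calls that were also lost without control replicate 3 and stood in 2 and 5 of the 6 refits. Of 27 chemokine and cytokine genes, Il34 and Cxcl14 were called, and of 17 complement genes the 3 given above. The chemokine count was 1 without control replicate 2 or CXCL12-deficient replicate 2, 0 without control replicate 3 and 3 without CXCL12-deficient replicate 1 or 3. The complement count was 1 without control replicate 2 or 3, and 2 to 4 without any other library. Adjusted over the list alone, 9 of the chemokine and 7 of the complement genes passed. No gene was called by edgeR in the hedgehog, hypoxia and glycolysis, oxidative phosphorylation, unfolded protein response, immediate early, imprinted, pericyte and smooth muscle, skeletal muscle or Schwann cell lists. Without control replicate 1, however, 1 imprinted gene was called, and without CXCL12-deficient replicate 2, 1 each of the pericyte, skeletal muscle and Schwann cell genes. Each of these lists held at most 4 genes at an unadjusted p below 0.05, at most 2 called by DESeq2 and none by limma-voom. Adjusted over the list alone, 5 Notch, 4 matrix, 2 CXCL12 receptor, 2 Wnt and 2 pericyte genes passed, and 1 each of the BMP, osteocyte, osteoclast, skeletal muscle and Schwann cell lists. None passed in the osteoblast, cartilage, erythroid, hedgehog, hypoxia, oxidative phosphorylation, unfolded protein, immediate early and imprinted lists. The most abundant immediate early gene, Fos, had 3674 and 4455 CPM (adjusted p = 0.61), and the chaperone gene Hspa5 had 2894 and 3137 CPM (adjusted p = 0.86). In total 13 of 32 lists passed camera with the preset correlation, and the others had adjusted p between 0.076 (cartilage) and 0.98. For the osteoblast, matrix, osteocyte, Notch, Wnt, BMP, imprinted, erythroid, Schwann cell and unfolded protein lists the median, the mean and the test differed in sign. No list passed with an estimated correlation (smallest adjusted p 0.23, 6 lists at an unadjusted p below 0.05), and 5 passed directional fry. Other splits of the same 6 libraries gave between 6 and 16 lists with the preset correlation.

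Libraries grouped by condition, and 1 differed in sex. The first principal component held 43% of the variance and separated the groups, and the second held 18.5% and set CXCL12-deficient replicate 3 apart from replicates 1 and 2. Across genes, log2 CPM correlated at 0.946 to 0.971 within controls, 0.939 to 0.943 within CXCL12-deficient libraries and 0.904 to 0.934 between groups. Genes are not independent replicates, and these values describe the libraries only. CXCL12-deficient replicate 2 was the only male library, with 1354 reads of the Y-linked gene Ddx3y and 8 of Xist. The other 5 had at least 2697 reads of Xist and at most 3 Y-linked reads. Without that library 488 genes were called.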

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

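The settings with the exon entries as deposited and with library size alone were chosen after seeing the data, and all others before. The number of genes changed, 637, was between 624 and 661 with DESeq2 size factors, upper quartile factors, no filter, the filter of 5 CPM, no robust shrinkage, limma-voom, exon entries as deposited or library size alone, and 855 with limma on the deposited log2 values. Lower calls made up 86% of all calls with TMM, and between 84.8% and 90.5% with the other scalings. The DESeq2 Wald test called 1328 genes, 300 higher and 1028 lower, with 934 changed at least 2-fold; it shared 636 of the 637 genes, and the cause of its higher count was not tested. Limma on the deposited log2 values, which are shrunken by construction, gave 293 genes changed at least 2-fold. An adjusted p below 0.01 left 80 genes. Limma-voom called 624 genes, of which 570 were shared.

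Leaving out 1 library gave 74 to 577 genes changed, 0 to 76 higher, 74 to 530 lower and 74 to 529 changed at least 2-fold. The lowest values came without control replicate 3, and the cause was not tested. The Cxcl12 log2 fold change was between -1.62 and -1.47 in these refits, and its adjusted p was between 6.3e-21 (DESeq2) and 0.025 over all settings. Gene lists past the threshold numbered 12 to 14 without a library, and 11 to 13 with the other scalings, filters, exon entries or deposited log2 values, all with the preset correlation. With an estimated correlation 0 lists passed, and 5 passed directional fry, which does not compare a list with other genes. The DESeq2 Wald test, limma-voom and no robust shrinkage had no gene list value, since camera ran on voom values and takes nothing from the tests of single genes. Of 67 named genes and exons past the threshold, 13 were called in every refit without a library, among them Cxcl12 and its exons 2, 3 and 4, C3, Cd34, Esam, Ly6c1, Lyz2, Pf4, Ppbp and Ptprc. Among the named genes and exons, calls were lost for 10 with limma-voom, 4 each with no filter and with library size alone, 2 each with DESeq2 size factors and with the deposited log2 values, and 1 each with the filter of 5 CPM and with DESeq2. The filter of 5 CPM also removed called genes at low levels, among them Cdh5, Sox17 and Cfd, and these are not counted as lost. No called value reversed in any setting. None of the 67 changed sign without a library, which their lack of overlap between the groups all but fixed in advance, and 3 were called in no refit. The 3 libraries per group limit the detection of moderate changes: the simulated comparison of 13684 independently drawn genes recovered 28.4% of 2-fold changes.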

Other observations

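The following called genes lie outside the fixed lists and were chosen after their values were seen. They were not tested as a group and do not stand for a pathway. Thrsp and Mlxipl, which encode regulators of fatty acid synthesis, were 14.2-fold and 11.8-fold higher from control means of 0.624 and 0.352 CPM (adjusted p = 0.024 and 0.015). Thrsp varied between 2.04 and 17.0 CPM among CXCL12-deficient libraries, and Mlxipl between 3.87 and 4.80 CPM. Nr1h3 (the sterol receptor LXR alpha) was 1.83-fold, Aqp7 (a glycerol channel) 1.79-fold, Bscl2 (seipin, of lipid droplets) 1.68-fold and Acadm (of fatty acid oxidation) 1.55-fold higher. Acly, which makes cytosolic acetyl-CoA for fatty acid synthesis, fell by 0.79 on the log2 scale (adjusted p = 0.020), as Dgat2 did. Fth1 (ferritin heavy chain) and Hfe (a regulator of iron uptake) were 1.73-fold and 1.88-fold higher, Fth1 from 3276 ± 53.2 to 5653 ± 910 CPM (SD, n = 3).

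The patterns below were weighed with tests of which those on depth, even loss, dilution and the 4 exons were chosen only after the result was seen. The correlations of single lists with the neutrophil list were also added afterwards, and the granulocyte explanation was then narrowed.

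The first pattern was the fall of genes of blood and endothelial cells, which the erythroid list did not share. Shallower CXCL12-deficient libraries are argued against by a ratio of mean total counts of 0.983. One even loss of every other cell type is argued against by the erythroid list, whose median lay 2.04 above that of the neutrophil list on the log2 scale (95% bootstrap intervals over genes -0.22 to 0.23 and -2.29 to -1.98). These intervals are too narrow, since they leave out the spread between libraries and treat genes as independent. The estimated correlation between genes was 0.72 in the erythroid and 0.57 in the neutrophil list. Fewer cells of the granulocyte lineage among the sorted cells is a candidate explanation for the neutrophil genes and for part of the 489 lower genes outside the lists. Within groups, these 489 had a median correlation of 0.62 with the neutrophil list from library to library, positive for 80.8% of them. Random sets (1000) of uncalled genes outside the lists, matched on expression, reached at most 0.06. Those sets were drawn gene by gene, so genes that vary together for any reason would exceed them. The correlation of 0.62 does not single out granulocytes. The B lineage, erythroid and cell cycle lists followed the neutrophil list at medians of 0.88, 0.82 and 0.74, and the erythroid list did not fall. The endothelial, megakaryocyte, macrophage, T and NK cell, and fibroblast and tendon lists had medians of 0.17, 0.26, 0.28, 0.17 and 0.26. These medians cover all tested members, called or not. Whether the lower members of these lists followed the neutrophil list was not computed, so the granulocyte explanation is neither extended to them nor excluded for them. The most abundant neutrophil genes, Ngp and Ltf, were still at 1557 and 910 CPM in the CXCL12-deficient libraries, against 6142 and 3429 CPM in controls, although GFP gated both groups, and no neutrophil gene was in another list. Whether fewer such cells passed the second, tdTomato gate or fewer were bound to stromal cells without CXCL12 cannot be told apart here, because gate and genotype changed together.

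The second pattern was the rise of niche genes, of which 4 of 27 were called. The single male library was tested on the called niche members, and 4 of them (Apoe, Cxcl14, Adipoq and Ebf3) kept a log2 fold change above 0.5 without it. Called genes did not overlap between the groups, so this outcome was nearly fixed in advance. The median log2 fold change of the niche list was 0.53 without the male library and 0.45 with all libraries, which argues against that library as the source of the rise. Without it Cxcl14 had adjusted p = 0.064 in edgeR. Dilution of stromal reads by other cells in the controls stays open: the niche median exceeded that of osteoblast and matrix genes by 0.43 (95% bootstrap interval over genes 0.32 to 0.73), but by 0.13 without control replicate 1, and CXCL12-deficient replicate 2 lay below 2 controls in the difference of list means. The wider control gate instead of loss of CXCL12 also stays open, since 0 libraries had gate and genotype apart, and their effects cannot be told apart. A biological response to lost CXCL12 was thus not tested separately from a difference between Col2a1-descended cells and the whole GFP+ population.

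The third pattern was the uneven fall of the 4 Cxcl12 exons. Fewer Cxcl12-expressing cells would lower all exons by the same factor. Exon 2, however, lay below exon 1 by a difference of -3.12 ± 0.26 in log2 fold change (SE). This SE and those below treat the exons as independent, although the same libraries gave all of them. Within libraries, the log2 ratio of exon 2 to exon 1 differed by -3.15 between the groups, and that of exon 3 to exon 4 by -1.15. Exact permutation gave p = 0.1 for each, the smallest this design allows. Cells without recombination as the source of all remaining reads would leave equal shares of every exon, but exon 4 kept 5.5 times the share that exon 2 kept. A remaining transcript that skips exon 2 and holds exons 1, 3 and 4 alike would leave equal shares of those exons. Exon 3, however, differed from exon 4 by -1.15 ± 0.23 and from exon 1 by -1.80 ± 0.21. This argues against such a transcript only if reads across exon borders were assigned alike in both groups, which was not tested. In the annotation exon 3 spans 87 bp, so many of its reads may cross a border. A mixture of transcripts from the recombined allele and from the GFP allele, or reads across the exon borders that were assigned to another exon, may explain the remainder and was not tested.

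Across the 10 splits of the 6 libraries into 3 and 3, the real one gave 637 changed genes and the highest of the others gave 0 in edgeR, with 186 to 945 genes at an unadjusted p below 0.05 against 2634. The real split was the only 1 with as many. Each other split mixed libraries of both conditions, so a real difference between the conditions would widen the spread within its groups and lower its calls. The 0 therefore does not measure what chance alone would give. For gene lists past the threshold with the preset correlation, the real split gave 13, the highest other gave 16, and 3 splits including the real one gave at least as many. With 10 splits the share cannot fall under 0.05.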
